A study of Homo sapiens with 2 samples.

How the data were processed

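ZFX ChIP-seq was measured in DAOY cells in 2 samples, the ZFX precipitation and the input, with 1 library each. Samples were grouped by the antibody named in the labels. The submitters' processing notes name Bowtie2 2.0.0 and the build hg19 without their roles. They were taken here as the aligner and the build of the positions. The deposited peak list has no header. Its peak names carry the name of the caller MACS; the version, threshold and control of the calling are not given in the sources used here. Each peak has a start, an end and a score, which the authors deposited without a stated unit. The score was used to describe, rank and filter peaks within the list, and its medians were compared between close and isolated peaks and between chromosomes of the same list. Its lowest value was 50 and 28 peaks shared the value 3100, so order among the strongest peaks is poorly resolved. Starts were taken as counted from 0, as in BED files, and are printed counted from 1. Read depth and tag counts were not analysed here, so no counting error could be given for a peak.

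Before the data were examined, 8 results were planned, on promoters, gene lists, GC content, sequence motif and chromosomes, with 36 alternatives, 29 gene lists and a rule for named genes. All of them needed genes or sequence on hg19. The gene table used here is on GRCh38.p14, and positions were not compared between builds. None of the 8 results was run as written, no gene was named by the rule, and none of the gene lists was tested as a list. From the gene table only the number of protein-coding genes per chromosome was taken, 20033 in all, together with the 392 olfactory receptor genes recognised by symbol. The results reported here, their alternatives and the regions named were chosen after the data had been seen. Regions were named as the peaks above the score 3100, those at or above it near the longest peak-free stretch of their chromosome, the strongest peaks of chromosome X, the widest peaks, the richest windows and the region with the most peaks.

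Peaks were counted by their midpoint in windows of 1 Mb between the outermost peaks of each chromosome. Peaks per 100 genes were given 95% intervals by resampling the windows of a chromosome 10000 times, and a chromosome was said to differ when its interval left out the value of the 23 chromosomes compared. These intervals were not adjusted for the number of chromosomes except in 1 alternative. Only peak counts were resampled and the gene count was held fixed. The intervals, also that of the ratio of chromosome X to autosomes, therefore carry the uneven spread of genes along a chromosome as well. In 20 simulated lists of 14471 peaks spread evenly within chromosomes, chromosome X at 0.3 times and chromosome 14 at 1.5 times the rate of the others were recovered in 20 of 20 lists, and 25 of 420 comparisons of chromosomes simulated as equal were called. Peaks in the real list are clustered, which these simulations do not include. Random placements (100) kept the chromosome and the width of each peak. Correlations across chromosomes were tested by two-sided permutation with 100000 resamples, and ratios of median scores and the correlation of width and score by resampling 10 Mb blocks 1000 times. Shares of peaks have exact Clopper-Pearson intervals, which treat peaks as independent. Alternatives were the peaks above the median score, peaks joined when at most 1 kb apart, other windows and distances, other denominators, wider intervals, chromosome Y, and sets of chromosomes or peaks left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.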

Results

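Chromatin bound by ZFX, a zinc finger transcription factor encoded on the X chromosome, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in DAOY, an established human medulloblastoma cell line. The study held 2 samples. In the first, sheared chromatin was precipitated with an antibody against ZFX, and in the second, sheared chromatin without precipitation served as input. Peaks were analysed for the 1 ZFX library, and the input was not analysed here. With 1 library there was no replicate check, and intervals and tests below describe the spread over windows, chromosomes or peaks within this library. Read depth is not given in the sources used here, so the precision of single peaks is unknown. Positions were taken to be on the hg19 build, and the score of each peak is the authors' own.

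The question of where ZFX lies on chromatin in this line was addressed first by the peaks themselves. The list held 14471 peaks on 24 chromosomes, which covered 8.21 Mb. The median peak was 481 bp wide, and 1177 bp marked the 95th percentile of width. Scores started at 50 with a median of 109, and 6743 peaks (46.6%) scored under 100. Scores of 1000 or more were reached by 304 peaks (2.10%). Wider peaks had higher scores, with a median width of 299 bp in the lowest 25% of scores and 857 bp in the highest 25%. Across peaks, which are not independent replicates, the Spearman correlation of width and score was 0.840, with a 95% bootstrap interval over 10 Mb blocks of 0.831 to 0.849.

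The peaks with the highest scores were spread over 13 chromosomes. The score 3100 was shared by 28 peaks and exceeded by 3. With 28 peaks at 1 value and no stated unit, the list does not show whether these 3 are stronger than the 28. The largest score listed, 3233, belonged to a peak of 2555 bp on chromosome 1 (46767065 to 46769619). A peak on chromosome 17 (33478049 to 33478497) scored 3230 over only 449 bp, and a peak of 1578 bp on chromosome 7 (73587943 to 73589520) scored 3154. Chromosome 1 carried 5 of the 31 peaks at or above 3100, chromosome 17 carried 4, and chromosomes 2, 7 and 19 carried 3 each. Among all 14471 peaks, chromosome 1 held 1635 and chromosome 17 held 942. The counts at or above 3100 were not tested against those totals. Of these 31 peaks, 4 lay within 2 Mb of the longest peak-free stretch of their chromosome, a count that was not compared with the share of all peaks. On chromosome 20, a peak at 26189761 to 26190574 bordered that stretch and another at 26188772 to 26189521 lay 1053 bp from it, and on chromosome 16 a peak at 33962897 to 33964326 lay 1902 bp from it. The peak on chromosome 2 at 85197346 to 85199610 lay 511 kb away. No peak on chromosome X, which held 177 peaks, reached the score 3100. The same held for chromosomes 4, 5, 6, 8, 9, 10, 11, 13, 18 and Y, so it does not set chromosome X apart. The strongest X peaks lay at 108297216 to 108297875 with a score of 2626 and at 24167133 to 24168375 with a score of 2382. The next X peak scored 666. The widest peak of the list covered 9036 bp on chromosome 21 (9825383 to 9834418) with a score of 3100, followed by a peak of 5347 bp on chromosome 19 (13949343 to 13954689) with a score of 1775. The peaks named here were not screened for repeated sequence or other sources of false signal, and the input was not analysed. They are therefore not shown singly to be sites of ZFX.

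Peaks followed gene density across chromosomes. Chromosome 19 had the most peaks for its length, 16.6 per Mb of the span between its outermost peaks, followed by chromosome 17 with 11.6 and chromosome 22 with 10.9. Chromosome X had 1.16 peaks per Mb, chromosome 4 had 1.94 and chromosome 18 had 1.94. Over the autosomes and chromosome X (n = 23), peaks per Mb correlated with protein-coding genes per Mb (Pearson's r = 0.943, permutation p = 1.0e-05; Spearman's rho = 0.867, permutation p = 1.0e-05, the smallest that 100000 resamples can give). Adjusted by the Benjamini-Hochberg method over the 2 relations computed, both values were 2.0e-05. Without chromosomes 17 and 19, the 2 farthest from the median gene density, r was 0.851. Both measures share the span of the chromosome as denominator.

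Relative to the number of genes, chromosome X carried the fewest peaks among the 23 chromosomes compared. It held 177 peaks for 848 protein-coding genes, or 20.9 per 100 genes (95% bootstrap interval over 1 Mb windows 15.8 to 26.5). The autosomes together had 74.7 per 100 genes, and the ratio of X to autosomes was 0.280 (0.212 to 0.356). The median score was also lower, 86.3 on chromosome X against 109.1 on autosomes. Copies of chromosome X in this line were not measured here, so fewer copies cannot be told apart from less binding. Chromosomes 4, 8 and 11 also lay below the value of 72.4 for all 23 chromosomes, with 48.1 (38.5 to 58.6), 55.2 (43.0 to 69.6) and 57.7 (45.4 to 70.9) peaks per 100 genes. Chromosome 7 with 100.7 (83.3 to 120.4) and chromosome 14 with 105.1 (81.7 to 130.4) lay above it. The intervals of the other 17 chromosomes included it. Among these were chromosome 16 with 57.4 and chromosome 18 with 55.9, rates lower than that of chromosome 11. When the intervals were widened for 23 comparisons, chromosomes 4, 7 and X still lay apart and chromosomes 8, 11 and 14 did not. Per Mb of span in place of genes, chromosomes 7 and 11 did not lie apart. In that setting chromosomes 1, 17, 19 and 22 also lay above the value of all chromosomes, and chromosomes 2, 3, 10, 13 and 18 also lay below it. The interval of chromosome 11 also included the value of all chromosomes with 5 Mb windows and without olfactory receptor genes in the gene count. Chromosome 16 lay below it when close peaks were joined, among peaks above the median score and without olfactory receptor genes, and chromosome 18 did so in the last 2 of these settings. Chromosome 5 lay above it when close peaks were joined, and among peaks above the median score chromosome 9 lay above it and chromosomes 10 and 13 below it. Chromosome Y was left out after its interval of 0 to 61.9 peaks per 100 genes had been seen, because its 15 peaks spanned only 3.47 Mb. When it was included, chromosome Y lay below the value of all chromosomes, and 7 chromosomes lay apart in place of 6.

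**Figure D1:**
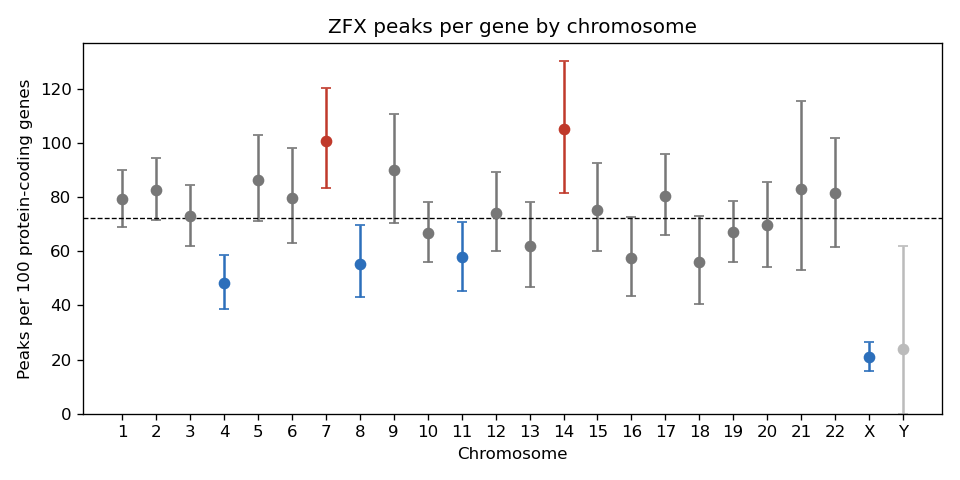
Peaks per 100 protein-coding genes (vertical axis) for each chromosome (horizontal axis) in the 1 ZFX library, with 95% bootstrap intervals over 1 Mb windows; the dashed line is the value of chromosomes 1 to 22 and X, red and blue mark intervals above and below it, grey marks intervals that include it, and pale grey marks chromosome Y, which was not compared. Chromosome X lies at 20.9, below the autosomes, which range from 48.1 to 105.1.

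Peaks were spread unevenly over windows, with a median of 3 per window. The richest 5% of 1 Mb windows, 148 of 2956, held 26.2% of the peaks, against 14.8% to 15.4% in 100 random placements of the same peaks on the same chromosomes. No peak fell in 773 windows (26.2%), against 3.89% to 5.14% of windows in the random placements, which did not leave out assembly gaps. The window with the most peaks, 51, lay on chromosome 11 between 65 and 66 Mb. It was followed by chromosome 17 between 79 and 80 Mb with 50 peaks and chromosome 19 between 1 and 2 Mb with 46. Of the 9 windows with 40 peaks or more, 3 lay side by side on chromosome 6 between 26 and 29 Mb, a part of the short arm known to hold the main cluster of histone genes. Together they held 129 peaks, 15.5% of the peaks of that chromosome, with a median score of 98.6 and a highest score of 667. No gene position was used here, so nothing ties these peaks to histone genes. The longest stretch without a peak between peaks was on chromosome X, where 23.6 Mb separated the peaks on either side.

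Many peaks also lay next to another one. Of all peaks, 4652 (32.1%, exact 95% interval 31.4% to 32.9%) were at most 1 kb from a neighbour, against 1.60% to 2.52% in the random placements. Joining such peaks gave 11962 regions, of which 9819 held 1 peak, 1850 held 2 and 293 held 3 or more. The region with the most peaks, 7, covered 7109 bp on chromosome 14 (75743291 to 75750399). The median score of close peaks was 101.4 and that of isolated peaks 112.6, a ratio of 0.901 (95% bootstrap interval over 10 Mb blocks 0.860 to 0.940). Of the 7227 peaks scoring above the median of the list, 2178 (30.1%, exact 95% interval 29.1% to 31.2%) had a neighbour of any score within 1 kb. Among the other peaks the share was higher, 34.2% (exact 95% interval 33.1% to 35.3%). The exact intervals treat peaks as independent although both peaks of a close pair are counted, so they are too narrow. The difference between these shares was not tested.

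**Figure D2:**
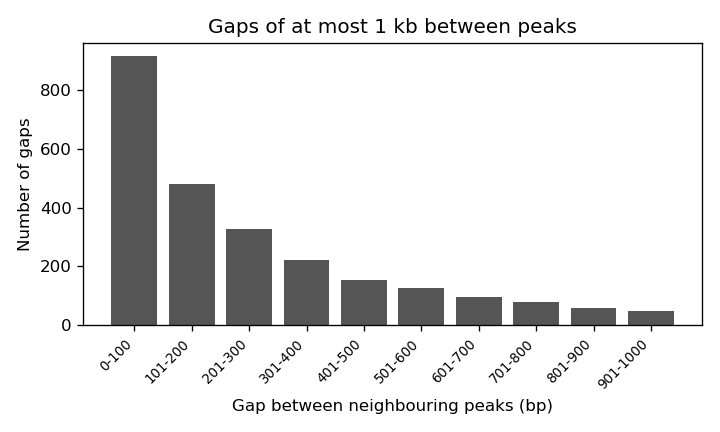
Number of gaps of at most 1 kb between neighbouring peaks (vertical axis) by length of the gap in bp (horizontal axis) in the 1 ZFX library; each bar is a class of 100 bp. The number falls from 914 gaps of at most 100 bp to 50 gaps of 901 to 1000 bp.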

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

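All results and alternatives in this part were chosen after the data had been seen, and none of the 36 alternatives set before the data were examined was run, because each needed genes or sequence on hg19. Of 30 alternatives for 7 results, 19 kept the call, or the value within its interval or 1.5 times the count. Some of these 19 could hardly change the value, as given below. A kept count of chromosomes could hold a different set of them, and a kept correlation could lie outside the interval of the main setting. The ratio of chromosome X to autosomes stayed below 1 with its interval in the 5 alternatives tried, between 0.214 and 0.287. Of these, 5 Mb windows could change only the interval. Leaving out olfactory receptor genes took 1 gene from chromosome X, so it could hardly change the ratio. Chromosomes called apart numbered 6 in the main setting, 11 among peaks above the median score, which included those 6, 13 per Mb of span, which shared 4 and left out chromosomes 7 and 11, and 3 with intervals widened for 23 chromosomes. The denominator and the interval width are the alternatives' own construction; for the higher scores the cause was not tested. Peaks with a neighbour made up 15.6% when both peak and neighbour had to score above the median, which lowers the share by construction, 27.2% at 500 bp and 39.9% at 5 kb. The richest 5% of windows held 27.1% of peaks above the median score, 24.5% of joined peaks, 29.5% with 500 kb windows and 19.9% with 5 Mb windows. The correlation of peaks per gene with median score across autosomes (r = 0.615) fell to 0.425 (permutation p = 0.0606) without chromosomes 4 and 14, was 0.635 to 0.740 in the other 3 alternatives across autosomes, and was 0.728 with chromosome X, whose median score was 86.3 against 109.1 on autosomes. The correlation of width and score was positive in its 3 alternatives, from 0.656 to 0.840. The value of 0.840 left out only the 31 peaks at or above 3100, so it could hardly differ from the main setting. Depth is unknown, so weak sites that were missed cannot be counted.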

Other observations

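All tests in this part were chosen after the results had been seen, and no explanation by a difference between groups was tested, since 1 group has peaks. On chromosome Y, 13 of 15 peaks (86.7%) lay within 20 kb, whereas the densest 20 kb of chromosome X held 7 of 177 (3.95%). The shares rest on unlike totals and spans, 3.47 Mb on chromosome Y and 152 Mb on chromosome X. Autosomes were not compared in this way. The strongest of the Y peaks scored 1822 over 227 bp.

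Chromosomes differed in peaks per gene. Of the olfactory receptor genes in the gene count, 1 lies on chromosome X, so leaving them out did not test its low value. Chromosome 11 carries 171 of them. Its rate was 0.797 (0.628 to 0.980) of that of all chromosomes before and 0.900 (0.708 to 1.11) after they were left out, at 66.5 peaks per 100 genes. Only the gene count changed and no peak was left out, so the rate had to rise wherever the peaks lay. The end of the call therefore does not show whether these genes account for the lower value. Unequal numbers of chromosome copies in this line would raise scores and peaks together, and across the 22 autosomes peaks per gene correlated with the median score (Pearson's r = 0.615, permutation p = 0.00233; Spearman's rho = 0.495, permutation p = 0.0206; adjusted over 2 relations 0.00233 and 0.0206). Across autosomes the value was 0.635 to 0.740 in 3 other settings, and without chromosomes 4 and 14, the 2 farthest from the median rate, it stayed positive but missed the threshold (r = 0.425, permutation p = 0.0606), a condition set after this value had been seen. Stronger binding on some chromosomes would give the same relation, so copy number cannot be told apart from binding with this list. The same holds for the low value of chromosome X.

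Some high-scoring peaks may come from repeated sequence beside the longest peak-free stretch of each chromosome, within 2 Mb. This was tried first on the 1% of peaks with the highest scores, of which 8 of 145 lay there (Fisher's exact test, odds ratio 1.76, p = 0.147), or 7 of 144 without chromosome Y (odds ratio 1.59, 0.623 to 3.39, p = 0.223). A second definition, set after that outcome and after the strongest peaks had been listed, took peaks in the top 5% of scores and no wider than the median, and 5 of 14 lay there (Fisher's exact test, odds ratio 16.8, p = 5.44e-05). Of those 14 peaks, 4 belong to the single cluster on chromosome Y. All 15 peaks of chromosome Y lie within 2 Mb of its stretch, so these 4 counted as near whatever their score. Without that chromosome 1 of 10 lay there (Fisher's exact test, odds ratio 3.44, 0.0783 to 24.9, p = 0.273). Nothing measured here ties these stretches to repeated sequence, and peaks from repeated sequence elsewhere would be missed. The peaks are also few in the second definition, so neither outcome decides the question. It stays open for all peaks named here. These include the peaks scoring 3100 on chromosomes 16 and 20 that lie at or within 2 kb of such a stretch.

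Peaks in close pairs may be single enriched regions cut into adjacent peaks by the caller. Of the 2509 gaps of at most 1 kb, 36.4% (exact 95% interval 34.5% to 38.3%) were at most 100 bp, against 10% if gaps were even, and no later step of 100 bp held as many. Separate sites that grow rarer with distance would also give such a decline, and this was not tested.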
